A study of Mus musculus with 82 samples.

How the data were processed

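RNA from laser-captured plasma cells and from whole sections of pristane granulomata was amplified in repeated linear rounds and hybridized to mouse oligonucleotide arrays, per the labels' protocols. The authors deposited 1 table of log2 values for 82 arrays and 22690 probe sets, normalized with RMA in Partek, per the submitters' processing notes. The versions of both are not given in the sources used here. Every column of the table belonged to a sample (columns of no sample, 0), and each array's tissue type, study and day were taken from its sample labels and its specimen code from its title. The title of 1 array of day 33 of study 1 held no code, and it was kept as its own specimen, as was code 003 of day 7, which could be code 3. The log2 values deposited by the authors ranged as RMA values do, with column medians between 4.973 and 7.335, and were not logged again. Scanner images and unnormalized probe intensities were not used here.

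Probe sets were named with the gene table given for the array, matched to current symbols by gene identifier where possible (20364 probe sets). 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none listed, and 64 were control probe sets. A gene was represented by its probe set with the highest mean over all arrays among those with 1 symbol, which gave 12394 genes. A gene was tested when its value was above the median of all probe sets of the column in at least 3 specimen averages, which left 8593 genes. Other probe sets of a gene that were past the threshold in the opposite direction are stated where the gene is named. Those that moved less or did not pass are stated for some genes only, so that the sizes given are those of 1 probe set.

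Arrays of 1 specimen code and tissue type were averaged, because their titles give them 1 number. Some titles add a letter to the number, which the code leaves out. The letters differ within 4 codes of study 2 and 3 of study 1, and the sources used here do not say whether these arrays share a specimen. The 2 arrays of code 5 of day 7 of study 1 had opposite sex-linked transcripts (Eif2s3y at 2.83 and 7.70, Xist at 11.65 and 4.90), which 1 animal does not explain. Their average was kept, and the code was also run as 2 specimens. This gave 53 averages from 33 codes in 19 groups of study, tissue type and day, of which 20 codes had both tissue types. All groups entered a single fit with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 34 residual degrees of freedom), with the specimen code as a random block (duplicateCorrelation, 0.121 on the deposited values and 0.112 on quantile-normalized values). The Benjamini-Hochberg adjusted p threshold was 0.05. Captured cells and whole granuloma were compared as the mean over the days of a study with equal weights, the studies were compared by an interaction over the shared days, the days were compared by moderated F tests within a tissue type, and the last day was compared with day 7. For small groups such as day 104 of study 1, with 1 specimen, the spread is that of the pooled fit.

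The plan fixed before the data were examined used the values as deposited throughout. The medians of the deposited columns differed between tissue types by more than most gene differences, so the comparisons of captured cells with whole granuloma were made on values quantile-normalized across all arrays (limma normalizeBetweenArrays), a departure from the plan that was made after the data were seen. The deposited values and median centring are given beside those results. All comparisons over days, and the difference between the changes of the tissue types, used the values as deposited.

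Gene lists were tested with camera on values and design whitened by the block correlation, with a preset gene correlation of 0.01 and, as an alternative, an estimated correlation, adjusted over the 34 lists of a comparison. A total of 33 lists were fixed beforehand by symbol and the list of immunoglobulin genes held all symbols starting with Igh, Igk or Igl except Ighmbp2. They covered plasma cells, B cells, T and NK cells, macrophages, neutrophils, dendritic cells, mast cells and eosinophils, fibroblasts and collagen matrix, endothelium, mesothelium, adipocytes, pancreatic acinar cells, intestinal epithelium, smooth muscle and erythroid cells, and Myc targets and ribosome biogenesis, cell cycle, unfolded protein response and secretion, IL-6 and STAT3, NF-kB, interferon response, inflammatory cytokines and chemokines, plasma cell niche factors, lymphoid tissue organisation, MHC class II, complement, matrix remodelling, lipid handling, p53 response, glycolysis, oxidative phosphorylation, ribosomal protein and immediate early stress genes. The genes to name were also fixed beforehand: the 6 largest increases and 6 largest decreases past the threshold with the same sign in the other study where it has the contrast (immunoglobulin genes left out and described as a group), up to 4 members of each list with the largest change past the threshold (or up to 2 with the smallest p where none passed), the 6 smallest p-values of each F test, and Myc, Sdc1, Xbp1, Irf4, Prdm1, Il6, Il6ra, Stat3 and Mki67 in every comparison. Part of these genes are not named, for length. The levels of Eif2s3y, the day 7 value of Cpb1 by specimen, the study 1 and study 2 values beside each difference, and the comparison by probe set of Ighm were chosen after the values were seen.

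The difference between 3-prime and 5-prime control probe sets of Gapdh and Actb was taken as a sign of RNA quality per array. The specimen code pairs the tissue types by the number in the titles. With the letter as part of the code 18 specimens had both tissue types. Deviations from the group means correlated between the tissue types of a code by −0.197 to 0.67 in the 15 pairs of study 2 (mean 0.187, above 0.1 in 10) and by 0.0357 to 0.273 in 4 pairs of study 1 (above 0.1 in 2).

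Each test was run on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. Of these, 96% and 100% were recovered for captured cells against whole granuloma in study 2, 82% and 100% in study 1 and 55% and 94% for the difference of the studies. For day 105 against day 7 the shares were 33% and 86% in captured cells and 36% and 85% in whole granuloma. For days 46 and 49 against day 7 they were 70% and 94%. For the F tests of studies 2 and 1 they were 30% and 82%, and 30% and 81%, in captured cells. In whole granuloma they were 34% and 93%, and 32% and 87%. For the difference of the changes they were 7% and 57% and for the variation by day 5% and 68%, so that smaller differences would mostly be missed there. Calls on unchanged genes were above the intended 5% in whole granuloma of study 2. They were 21 of 142 (14.8%) for day 105 against day 7 and 30 of 157 (19.1%) for the F test. They were at most 2.46% elsewhere. In captured cells of study 2 real counts fell with only their arrays fitted (day 105, 586 to 80), so this may not hold. For captured against whole and the difference of the studies, the simulated sets had equal means apart from the changed genes. They held no scaling or RNA quality difference between tissue types and were not quantile-normalized, so their shares do not carry over to real data.

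Alternatives covered arrays entered singly or as independent samples, no block, a fixed block of the specimen code (specimens with both tissue types only) or of the number 1 to 3, no filter or a stricter one, other scalings, all probe sets or only unambiguous ones, array weights, a trended and robust eBayes, fits of only the samples concerned, 2 uncoded arrays left out, the RNA quality covariate, the period of the dates in the titles with arrays entered singly, and each specimen left out in turn. The sources used here do not say what these dates mark, and arrays without a date were put in the earliest period. After the data were seen, the compressed array left out, a specimen split by its 2 arrays, the letter of the titles as part of the code, median centring, the last day left out, and list tests without specimen 1 of day 7 of study 2 were added. Counts were also compared with those of up to 100 other splits of the samples.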

Results

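Gene expression was measured on mouse oligonucleotide arrays in inflammatory granulomata of BALB/c mice that carried an iMycEμ transgene (a Myc gene inserted in the immunoglobulin heavy chain locus) and had received pristane, a mineral oil that induces peritoneal plasma cell tumors in such mice. Plasma cells stained with methyl green pyronin were taken from the sections by laser capture, and undissected sections of the granulomata gave whole granuloma RNA. 82 arrays came from 2 independent cohorts. Study 1 held 25 arrays of captured plasma cells (days 7, 17, 33, 46 and 104) and 12 of whole granuloma (days 7, 17, 33 and 104). Study 2 held 30 arrays of captured plasma cells and 15 of whole granuloma (days 7, 17, 33, 49 and 105). The arrays came from 33 specimen codes, and 20 of them had arrays of both tissue types. The day groups held 3 specimens each in study 2. In study 1 the captured cells of days 7, 17, 33, 46 and 104 came from 4, 4, 3, 3 and 1 specimens, and the whole granuloma of days 7, 17, 33 and 104 from 2, 2, 3 and 1. These counts take code 003 of day 7 and an array of day 33 without a code as specimens of their own, although 003 could be code 3 of that day. All day 104 arrays of study 1 carried the code 4687. The median log2 value of the arrays lay between 5.309 and 5.641 in captured cells of study 2 and between 7.113 and 7.335 in whole granuloma of study 2. In study 1 it lay between 4.973 and 5.111 in captured cells and between 5.727 and 5.825 in whole granuloma. The number of specimens limits the precision of every value given here.

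The comparison of captured cells with whole granuloma asked which transcripts separate the plasma cells from undissected sections, which hold plasma cells too. Study 2 had 15 specimens of each tissue type. Captured cells held more Mrpl47 transcript, which codes for a mitochondrial ribosomal protein (log2 9.85 ± 0.27 against 6.73 ± 0.79, SD, higher in 15 of 15 specimens, an 8.69-fold difference). They also held more Malat1, a nuclear noncoding RNA (10.61 ± 1.02 against 7.40 ± 1.01, 15 of 15 specimens, a 9.29-fold difference). Transcripts of fat and smooth muscle were lower. Adipoq, the fat hormone adiponectin, differed by −5.15 on the log2 scale (SE 0.55, adjusted p = 1.4e-10, lower in 14 of 15 specimens). Car3 differed by −4.94 (SE 0.64), the lipogenic factor Thrsp by −4.55 (SE 0.52) and the smooth muscle actin Actg2 by −4.43 (SE 0.51). Cyp2e1 (−5.12) and Cidec (−4.61) were the other largest decreases. Rpgrip1 (2.78), Cenpk (2.73), Agbl5 (2.70) and Zfp53 (2.54) were the other largest increases. Another probe set of Rpgrip1 (0.85) and of Agbl5 (0.55) passed with a smaller size. Of 4 other Malat1 probe sets (−0.31 to 2.71) 2 passed. Of 8593 genes tested with limma, 5998 were past an adjusted p of 0.05, 2959 higher and 3039 lower. Of these, 699 and 928 differed at least 2-fold. 4494 of the 5998 (74.9%) had the same sign in study 1, against 68.8% of all genes.

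Plasma cell genes took both directions in study 2. Of 17 tested, 6 were higher, 3 lower and 8 not past the threshold, and the list as a whole had an adjusted p of 0.427 (camera). Higher were Eaf2 (log2 difference 2.19, SE 0.23) and the surface receptor gene Slamf7 (1.46, SE 0.14, adjusted p = 1.3e-11, 15 of 15 specimens). Prdm1 (0.66, SE 0.19) and Xbp1 (0.62, SE 0.10), which code for factors that drive plasma cell differentiation, were higher too, as was the plasma cell surface proteoglycan gene Sdc1 (0.46, SE 0.13). Tnfrsf13b, a receptor for B cell survival factors, was lower (−0.69, SE 0.18). Mki67, a marker of dividing cells, was higher (0.96, SE 0.18), and Myc did not pass (0.05, SE 0.16, adjusted p = 0.78). Immunoglobulin genes split as 3 higher and 9 lower of 17 (list adjusted p = 0.387). Igkv19-93 was at 1.94 and Igk at 2.29, where 2 other Igk probe sets were past the threshold in the opposite direction. B cell genes were higher in 2 and lower in 5 of 11 (list adjusted p = 0.637), with Cd37 at −1.32 and Fcrla at 1.08. Another probe set of Cd37 (0.002) and of Fcrla (−0.08) did not pass.

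9 gene lists as a group were lower in captured cells of study 2 with a preset gene correlation, and each named another cell type or a general function. None of the 9 passed with an estimated gene correlation: adjusted p = 0.406 with an estimated correlation for complement and adjusted p = 0.855 with an estimated correlation for each of the other 8. All 9 adipocyte genes were lower (median −2.78, adjusted p = 0.000294), as were all 9 smooth muscle genes (median −3.37, 0.000589), with Myh11 at −4.36 and Tagln at −3.63. All 9 complement genes were lower too (median −1.37, 0.000294), with Cfb at −3.49 (SE 0.18, 15 of 15 specimens). Macrophage genes were lower in 16 and higher in 1 of 22 (median −0.86, 0.00777), with Arg1 at −2.17, Cd68 at −1.84 and Gpnmb at −1.76. Antigen presentation genes of MHC class II were lower in 7 of 8 (median −1.75, 0.0181), with Cd74 at −2.28 and H2-Aa at −1.84. Mesothelium genes were lower in 7 and higher in 1 of 9 (0.0233, Krt19 at −2.93, Msln at −2.38). Endothelium genes were lower in 10 and higher in 1 of 14 (0.0244, Lyve1 at −1.60, Vwf at −1.52). Glycolysis genes were lower in 9 of 11 (0.0244, Aldoa at −1.58, Pkm at −1.53) and immediate early stress genes in 10 of 12 (0.0271, Zfp36 at −1.66, Egr2 at −1.55).

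The other lists of study 2 did not pass as a group. Fibroblast and collagen matrix genes were lower in 11 and higher in 5 of 19 (adjusted p = 0.291, Fbln1 at −1.94, Sparc at −1.61). Lipid handling genes were lower in 8 and higher in 1 of 14 (0.103, Apoe at −1.90), and matrix remodelling genes lower in 7 and higher in 1 of 12 (0.17, Mmp14 at −1.35). Neutrophil genes were lower in 7 and higher in 3 of 12 (0.427, Lcn2 at −1.70). Genes of IL-6 and STAT3 signalling were lower in 8 and higher in 4 of 16 (0.427). The cytokine Il6 itself was at 0.80 (SE 0.29) and the kinase gene Jak1 at −1.30, where another Jak1 probe set was past the threshold in the opposite direction. Myc targets and ribosome biogenesis genes were higher in 11 and lower in 7 of 24 (0.653, Nop56 at 1.43, with another probe set not past at 0.05). Cell cycle genes were higher in 11 and lower in 4 of 23 (0.37, Bub1 at 1.27). Genes of the unfolded protein response and secretion were higher in 5 and lower in 7 of 22 (0.895, Pdia4 at −1.39). NF-kB genes were higher in 3 and lower in 5 of 10 (0.567, Relb at −1.32). Interferon response genes were higher in 2 and lower in 3 of 13 (0.743, Ifit1 at 1.04). Inflammatory cytokines and chemokines were higher in 4 and lower in 5 of 16 (0.977, Ccl12 at 1.22). Plasma cell niche factors were higher in 3 and lower in 2 of 10 (0.765, Cd80 at 1.07). Lymphoid tissue organisation genes were lower in 1 of 4 (0.602, Ltbr at −1.02).

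Among general functions and the remaining cell types of study 2, p53 response genes were higher in 3 and lower in 2 of 9 (0.637, Gadd45a at −2.35). Oxidative phosphorylation genes were higher in 4 and lower in 5 of 14 (0.765, Atp5b at −1.90). T and NK cell genes were higher in 1 and lower in 2 of 9 (0.916, Zap70 at 0.73), and dendritic cell genes higher in 2 and lower in 2 of 6 (0.776, Flt3 at 1.07). Mast cell and eosinophil genes were higher in 1 and lower in 2 of 5 (0.567, Kit at −1.43), and pancreatic acinar genes higher in 2 of 9 (0.46, Prss2 at 0.93, a call that held with 8 of 15 specimens left out in turn). Intestinal epithelium genes were lower in 3 of 3 (0.427, Epcam at −1.24), and the 1 tested erythroid gene, Alas2, was lower (−1.24, list 0.567). Ribosomal protein genes were higher in 2 and lower in 5 of 8 (0.475). Of these, Rplp0, Rps2 and Rpl8 were lower with quantile normalization (−0.77, −0.63, −0.53) but higher than the median gene on the deposited values (0.38, 0.55, 0.54) and with median centring (0.58, 0.74, 0.74). Adjusted over the list alone, most counts of study 2 were the same. They differed for neutrophil genes (3 higher, 8 lower), fibroblast genes (6 higher, 12 lower), T and NK cell genes (1 higher, 0 lower) and mast cell genes (2 higher, 2 lower). They also differed for acinar genes (0), unfolded protein response genes (5 higher, 5 lower) and interferon genes (2 higher, 2 lower).

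The scaling between tissue types and a covariate for RNA quality both changed the study 2 comparison. On the values as deposited the median gene was lower in captured cells by −1.68 on the log2 scale, with 44 genes higher and 8273 lower. With each array centred on its own median 3926 were higher and 2326 lower. The difference between the 3-prime and 5-prime control probe sets, a sign of RNA degradation or short amplification products, was 4.14 ± 0.90 (SD, 30 arrays) in captured cells and 1.61 ± 0.13 (15 arrays) in whole granuloma. With this difference as a covariate 3452 genes were past the threshold (1184 higher, 2268 lower). Eaf2 (0.54), Xbp1 (0.14), Prdm1 (0.27), Sdc1 (0.02) and Mki67 (0.04) no longer passed with it. The same held for 4 of the largest decreases, Adipoq (−3.56, adjusted p = 0.067), Cyp2e1 (−3.13, 0.085), Thrsp (−3.02, 0.099) and Car3 (−3.45, 0.13), while Cidec and Actg2 passed. It also held for Tnfrsf13b, Igk, Fcrla, Arg1, Lyve1, Vwf, Egr2, Epcam, Nop56, Ifit1, Ccl12, Cd80, Il6 and Prss2. Of these, Igk (2.19 to 2.45), Vwf (−1.75 to −1.42) and Il6 (0.70 to 1.6) kept about their size or more under every setting. Their lost call does not speak for RNA quality as the source. The others of this group shrank more under some setting.

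In study 1, with 15 specimens of captured cells and 8 of whole granuloma, the largest decreases in captured cells were again those of smooth muscle and fat. Actg2 was at 3.51 ± 0.23 against 9.03 ± 1.71 (SD, lower in 5 of 5 specimens with both tissue types, log2 difference −5.86, SE 0.72). The captured level of Actg2 lay near the floor of the arrays, so that the size of its difference is not exact. The differences of study 1 average days 7, 17, 33 and 104, at which both tissue types were measured. The fatty acid desaturase gene Scd1 differed by −5.74 (SE 0.52), Thrsp by −5.39, Myh11 by −5.16 (SE 0.54), Adipoq by −4.96 (SE 0.79) and Myl9 by −4.74. Rab26os (2.76, SE 0.25), Mrpl47 (2.69, SE 0.23, 5 of 5 specimens) and the mitochondrial ribosomal gene Mrpl33 (2.54, SE 0.14) led the increases. Tes3-ps (2.44), the transcription factor gene Tfap4 (2.37, SE 0.12) and Pet100 (2.28) followed. Of the 17 plasma cell genes 5 were higher and 0 lower (3 higher adjusted over the list alone, list adjusted p = 0.275). These included Slamf7 (1.48, SE 0.20, 5 of 5 specimens, adjusted p = 9.9e-08), Eaf2 (1.21, SE 0.33) and Derl3 (0.81, SE 0.24), a gene of protein degradation in the endoplasmic reticulum. Sdc1 (0.40, adjusted p = 0.053), Xbp1 (0.01), Prdm1 (0.15), Mki67 (0.01) and Myc (0.43, SE 0.22, adjusted p = 0.088) did not pass. 5197 genes were past the threshold in study 1, 2706 higher and 2491 lower, 728 and 1173 of them by at least 2-fold.

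13 lists passed as a group in study 1. None of them passed with an estimated gene correlation, where the values ranged from adjusted p = 0.621 with an estimated correlation for complement to adjusted p = 0.73 with an estimated correlation for cell cycle and Myc targets. Cell cycle genes were higher in 13 and lower in 0 of 23 (median 0.74, adjusted p = 0.00789), with Ube2c at 1.38, Birc5 at 1.34 and Cdc20 at 1.31. Myc targets and ribosome biogenesis genes were higher in 12 and lower in 1 of 24 (median 0.51, 0.0109, 11 and 1 adjusted over the list alone), with Ppan at 1.85, Cad at 1.45 and Rrs1 at 1.22. Adipocyte genes (9 of 9, 1.67e-05), smooth muscle genes (9 of 9, 0.000167) and macrophage genes (18 of 22, 1.67e-05) were lower, with Arg1 at −3.91 (SE 0.48), Gpnmb at −2.63 and Cd14 at −2.43. Complement (7 of 9, 0.000459, Cfb at −3.03), fibroblast and collagen matrix (13 of 19, 0.000459, Lum at −2.14) and lipid handling genes (8 of 14, 0.00212, Cd36 at −3.29) were lower as well. The same held for mesothelium (7 of 9, 0.00485, Upk3b at −3.51) and interferon response genes (8 of 13, 0.0293, Oasl2 at −2.23, 10 adjusted over the list alone). Matrix remodelling genes were lower in 9 and higher in 1 of 12 (0.0373, Mmp12 at −2.42). Pancreatic acinar (6 of 9, 0.0373, Cpb1 at −2.90) and immediate early stress genes (6 of 12, 0.0449, Klf4 at −1.96) completed the list. The counts adjusted over the list alone were otherwise the same. The cytokine genes Il1b (−2.85, SE 0.28) and Il6 (−1.26, SE 0.41) were lower in captured cells, and the receptor gene Il6ra was higher (1.27, SE 0.25). Ighg3 was at −3.12 (SE 0.82) and Ighm at −1.75 (SE 0.45), for which 1 other probe set was past the threshold in the opposite direction. With day 104, which had 1 specimen, left out neither passed. Ighm was then at −0.18 (adjusted p = 0.74) and Ighg3 at −1.46 (adjusted p = 0.11), while Gpnmb was at −1.54 and still past the threshold.

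3139 genes were past the threshold in both studies with the same sign, 1593 higher and 1546 lower, against 931.8 and 881 for independent calls, and 679 were past with opposite signs. At least 2-fold in both were 207 higher and 442 lower genes. The shared decreases held the fat genes Adipoq, Scd1 and Thrsp and the complement gene Cfb, and the shared increases Mrpl47, Slamf7 and Eaf2. On the deposited values, where the median gene of study 1 was lower in captured cells by −0.60, 659 genes were higher and 5177 lower in study 1, and 17 were higher and 5144 lower in both studies. With each array centred on its median the shared counts were 2161 and 1208. The 3-prime to 5-prime difference was 4.50 ± 0.69 (SD, 25 arrays) in captured cells and 3.19 ± 0.36 (12 arrays) in whole granuloma of study 1, and with it as a covariate 1848 genes passed in both studies, 672 higher and 1176 lower, and 4148 in study 1, 1734 higher and 2414 lower, so that the even split of the directions did not hold. Eaf2 passed in neither study (0.34 in study 1). In study 1 the cell cycle genes Cdc20 (0.21) and Birc5 (0.59) and the Myc target Cad (0.59) did not pass with it, nor did Derl3 (0.77) and Il6 (−0.83), and Ube2c did (1.15).

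**Figure D1:**
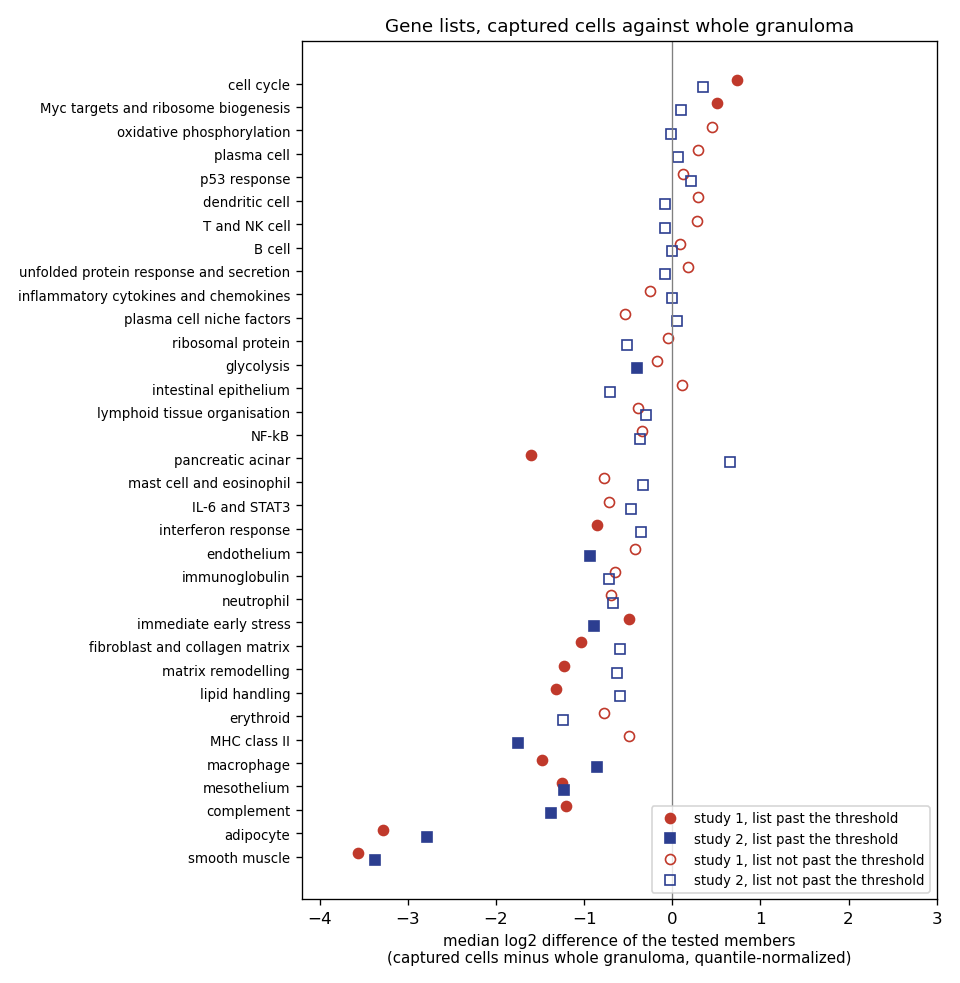
Median log2 difference between captured cells and whole granuloma (x axis, quantile-normalized values) of the tested members of each of 34 gene lists (y axis), for study 1 (red circles) and study 2 (blue squares), filled where the list passed an adjusted p of 0.05 with the preset correlation. Smooth muscle (−3.56 and −3.37) and adipocyte genes (−3.28 and −2.78) lie lowest in both studies, and on the deposited values all genes shift, with a median of −0.60 in study 1 and −1.68 in study 2.

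Whether the difference between captured cells and whole granuloma was the same in both studies was tested over the 4 days they share. Digestive enzyme genes of the pancreas were lower in captured cells of study 1 and not of study 2. Cpb1 differed by −2.90 in study 1 and 0.72 in study 2 (difference 3.52, SE 0.88, adjusted p = 0.00128). Cpa1 differed by −2.65 and 0.77 (difference 3.49, SE 0.76) and Ctrb1 by −2.21 and 0.56 (difference 2.89, SE 0.68). Single specimens weighed on the sizes for Cpb1, at 11.01 in captured cells of specimen 1 of day 7 of study 2 and 12.64 in whole granuloma of code 16 of study 1. The differences of the 3 genes passed with each of 26 specimens left out in turn. Serpinb6b (3.23, SE 0.44), Zg16 (2.96, SE 0.86) and Bmpr2, a receptor for bone morphogenetic proteins (2.91, SE 0.23, adjusted p = 1.33e-12), also had higher differences in study 2. Other genes had lower differences in study 2. The splicing factor gene Hnrnpl was at −1.74 in study 2 and 1.67 in study 1 (difference −3.62, SE 0.23). The RNA export factor gene Alyref was at −0.82 and 2.59 (−3.34, SE 0.25), Rsl24d1 at −2.05 and 1.27 (−3.35, SE 0.33) and Snd1 at −1.89 and 1.58 (−3.67, SE 0.35). Rraga, a gene of nutrient sensing, differed by −3.71 (SE 0.37) and Coq10a by −3.32 (SE 0.14). The study 2 values average its 5 days, and the difference uses the 4 shared days only.

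The test of the study difference was past the threshold for 3855 of 8593 genes, 1961 with higher and 1894 with lower values in study 2, 916 and 783 of them by at least 2-fold. The mannose receptor gene Mrc1 (difference 2.65, SE 0.29), Ifit1 (2.76, SE 0.46), Il1b (2.43, SE 0.36) and Il6 (2.17, SE 0.53) had higher values in study 2, and Il6ra (−1.30, SE 0.32), the epithelial adhesion molecule Epcam (−2.90, SE 0.42) and Rrs1 (−2.26, SE 0.28) lower ones. Xbp1 (0.68, SE 0.17, adjusted p = 0.00149) and Mki67 (1.01, SE 0.33, adjusted p = 0.0107) had higher differences in study 2, and Derl3 a lower one (−1.23, SE 0.31). Myc did not pass (−0.31, SE 0.28, adjusted p = 0.38). No list passed as a group (0 of 34), the lowest adjusted p being that of pancreatic acinar genes (0.0581, 7 of 9 higher and 8 adjusted over the list alone). On the deposited values 6231 genes passed (229 higher, 6002 lower), and with each array centred on its median 2593 had higher and 1595 lower values. With the RNA quality covariate the counts were 1460 and 2085, and Xbp1 (0.42) and Mki67 (0.50) did not pass. The whole granuloma arrays had a 3-prime to 5-prime difference of 1.61 in study 2 and 3.19 in study 1. Processing of the arrays and sex of the animals were not separated from the study here.

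The days after pristane were compared within captured cells on the deposited values. Genes of other cell types changed too, and admixed cells were not tested for. Klra17, a lectin-like receptor gene, rose from 6.05 ± 0.82 (SD, n = 3) at day 7 to 12.20 ± 0.54 at day 105 of study 2 (adjusted p = 6.3e-07 over the days), with 9.83 ± 1.22 at day 33 and 8.27 ± 0.75 at day 49. In study 1 it rose from 5.32 ± 1.15 (n = 4) at day 7 to 8.81 ± 0.74 (n = 3) at day 46 and 11.56 (n = 1) at day 104 (adjusted p = 0.00025). Ighm, the heavy chain of IgM, went the other way. It was at 14.67 ± 0.03 at day 7 and 8.17 ± 0.76 at day 105 in study 2, and at 14.36 ± 0.07 at day 7 and 6.78 at day 104 in study 1. Its day 7 values lay at or near the highest of their arrays in both studies, so that the sizes are not exact. Gpnmb, a glycoprotein gene of macrophages, passed over the days of study 1 with its highest mean at day 46 (9.15, against 6.98 at day 7 and 4.97 at day 104). In study 2 Entpd1 had the smallest p (adjusted p = 1.3e-08). It codes for an enzyme that breaks down extracellular ATP and rose from 6.67 ± 0.27 at day 7 to 9.17 ± 0.29 at day 105. Bmi1, a gene of the Polycomb group (9.67 ± 0.54 to 12.47 ± 0.31), and Osbpl1a (6.59 ± 0.39 to 9.95 ± 1.01) rose, and the signalling adaptor gene Stap1 fell (6.55 ± 0.44 to 4.42 ± 0.39). In study 1 the noncoding RNA Meg3 and Itih5 also passed and were lowest at day 104 (6.33 and 4.96, n = 1).

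**Figure D2:**
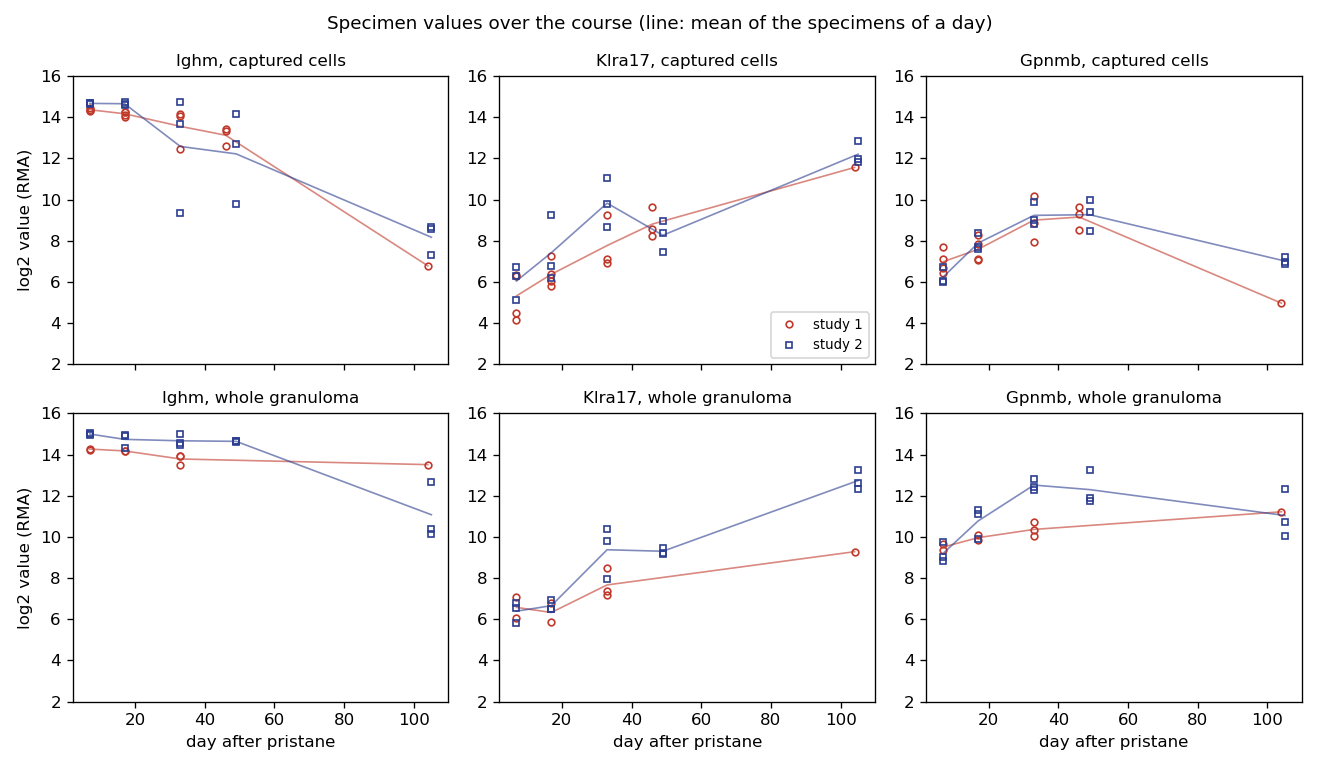
Log2 values of Ighm, Klra17 and Gpnmb (y axes) against the day after pristane (x axis) in captured cells and whole granuloma of both studies; each point is 1 specimen and the line joins the means of the days. In captured cells Klra17 lies highest and Ighm lowest at the last day of both studies, where study 1 has 1 specimen.

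Over the 5 days, 1304 genes changed in captured cells of study 2 (limma F test, 3027 at an unadjusted p of 0.05) and 51 in study 1 (882 unadjusted). Whether the counts of the studies differ was not tested. The mean 3-prime to 5-prime difference of the captured cells of study 2 was 4.66 at day 7, 4.69 at day 17 and 4.52 at day 33. It was 3.37 ± 1.09 at day 49, where the compressed array had 0.463 and the others 3.78 to 4.26, and 3.46 ± 0.29 at day 105. The Y-linked gene Eif2s3y was at 8.94 and 8.25 in captured cells of codes 11 and 12 of day 17 of study 1, and at 8.72 and 8.19 in those of the day 46 specimens with the middle and highest code. It lay between 2.76 and 3.54 in captured cells of study 2. Fitted with the captured arrays of 1 study alone, 33 genes passed in study 2 and 207 in study 1, and the study 2 count was 412 when 1 array of day 49 with compressed values was left out as well. Without specimen 1 or 3 of day 49 study 2 gave 2989 and 2914 genes, without specimen 2 or 3 of day 105 781 and 844. In study 1 the count was 27 without the day 46 specimen with the middle code and 31 without code 003 of day 7.

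From day 7 to day 105 of study 2, with 3 specimens at each day, Klra17 rose by 6.16 in captured cells (SE 0.68, adjusted p = 9.8e-08). The serpin gene Serpini1 rose by 3.40 (SE 0.49), Osbpl1a by 3.36 (SE 0.39), Bmi1 by 2.80 (SE 0.31) and Ttc8, a gene of the cilium, by 2.68 (SE 0.40). Klra5, of the same receptor family as Klra17, rose by 3.03 (SE 0.68), with 6.79 and 9.62 in specimens 2 and 3 of day 105 and 3.81 in specimen 1. The scavenger receptor gene Cd163 of macrophages fell by 3.75 (SE 0.53, adjusted p = 1.4e-05). The resistin-like gene Retnla fell by 3.05 (SE 0.73; 1.51 with array weights, adjusted p = 0.18, past under 12 of 16 settings), the G protein gene Gnai1 by 3.02 (SE 0.42), the phosphatase gene Dusp9 by 2.89, the matrix gene Dpt by 2.64 (SE 0.56) and Emb by 2.62. Among immunoglobulin genes, Ighm fell by 6.50 (SE 0.76, adjusted p = 2.2e-07) and Igk by 2.77 (SE 0.85). Igha, the heavy chain of IgA, rose by 5.34 (SE 1.00, adjusted p = 0.00072). The Igk call held with 3 of 6 specimens left out in turn. Igha was uneven at day 7, at 6.67, 14.20 and 6.39 in specimens 1, 2 and 3, and was 14.43 ± 0.46 at day 105. The Igha call was lost with array weights (2.33, adjusted p = 0.11), with only the captured arrays of study 2 in the fit (adjusted p = 0.14) and with the number 1 to 3 as a block (adjusted p = 0.18). The last 2 of these use the same specimen averages and leave the size at 5.34, so that only its spread differs. With the compressed array also left out of the fit of captured arrays of study 2 the Igha call was past (adjusted p = 0.041). Ighm at day 7 and Igha in specimens 1 and 2 of day 105 lay at or near the highest value of their arrays, so that the sizes of these changes are not exact. Klra5 was past under 12 of 15 settings. Of 7 other probe sets of Ighm, 1 was at −7.27 and the other 6 between −0.28 and 0.43. The change to day 104 of study 1 (1 specimen) was 6.25 for Klra17, 3.12 for Serpini1 and −7.58 for Ighm.

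Of 17 plasma cell genes 2 rose and 0 fell (also 2 adjusted over the list alone, list median 0.55, adjusted p = 0.0177). The list was not past with an estimated gene correlation (adjusted p = 0.939 with an estimated correlation). The 2 genes were Edem2, which helps to remove misfolded proteins (2.29, SE 0.39), and Tnfrsf13b (1.54, SE 0.41). Tnfrsf13c, the receptor for the B cell survival factor BAFF, rose by 1.66 (SE 0.33). Of the secretion genes Sel1l rose by 1.62 (SE 0.39) and Edem1 by 1.51 (SE 0.44). Fibroblast and collagen matrix genes fell in 4 of 19 (8 adjusted over the list alone, median −0.96, adjusted p = 4.26e-06), among them Postn by 2.61 (SE 0.37), Pdgfra by 1.57 and Fap by 1.44. This call was lost with adjusted p = 0.685 with an estimated correlation. Endothelium genes were lower as a group with 0 of 14 past the threshold (4 adjusted over the list alone, median −0.75, adjusted p = 0.000278, adjusted p = 0.685 with an estimated correlation). Pancreatic acinar genes (0 in both counts, median −1.74, 0.000278) and neutrophil genes (0 in both, median −0.74, 0.0175) were lower as a group too, both with adjusted p = 0.817 with an estimated correlation. Without specimen 1 of day 7 the acinar list was not past the threshold (median 0.05, adjusted p = 0.979). Adipocyte genes were lower as a group (0 and 1, median −0.82, 0.0177, adjusted p = 0.939 with an estimated correlation). The interferon response list was higher as a group with 0 of 13 past the threshold (4 adjusted over the list alone, median 0.88, 0.0175, adjusted p = 0.939 with an estimated correlation). In it Irf7 was at 1.49 (SE 0.49, adjusted p = 0.057). The immunoglobulin list was lower as a group with 1 gene up and 2 down (also adjusted over the list alone, median −0.42, 0.0386, adjusted p = 0.685 with an estimated correlation). Without specimen 1 of day 7 its median was −0.73 (adjusted p = 0.00587), and the macrophage list was then past the threshold too (median −0.40, adjusted p = 0.028 at the preset gene correlation). The lipid genes Fabp4 (−2.48), Cd36 (−2.20) and Lpl (−2.02) fell, and Myc did not pass (0.73, SE 0.41, adjusted p = 0.32). Without specimen 1 of day 7 the list of 14 lipid handling genes was not past the threshold (median −0.12, camera adjusted p = 0.135). Several of these calls were lost when 1 specimen was left out: Edem1 held in 1 of 6 cases, Pdgfra and Lpl in 2, Tnfrsf13b and Cd36 in 3 and Fabp4 in 4.

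Altogether 586 genes changed between day 7 and day 105 in captured cells of study 2, 382 up and 204 down, 282 and 175 of them at least 2-fold. The split was 233 and 180 with quantile normalization and 490 and 117 with RNA quality as a covariate, so that the balance of the directions depends on the processing. 479 of the 586 (81.7%) had the same sign in study 1 (60.7% of all genes), where day 104 was 1 specimen. 483 (82.4%, against 62.5% of all genes) had the same sign in whole granuloma of study 2. Both tissue types come from the same specimen codes, so that this agreement is not independent. At day 105 their deviations from the group means correlated by 0.473 to 0.67 within a code. The 3-prime to 5-prime difference was 4.66 ± 0.29 (SD) at day 7 and 3.46 ± 0.29 at day 105. Captured cells of specimen 1 of day 7 had Cpb1 at 10.97 against 3.52 and 3.55 in the other specimens of the day. The count was 128 without that specimen, 329 without specimen 2 of day 105, 80 when only captured arrays of study 2 entered the fit and 966 when the compressed array of day 49 was left out. Klra17, Serpini1, Osbpl1a, Bmi1, Ttc8, Cd163, Gnai1, Postn and Ighm passed under each of these and every other setting tried, on the chosen probe set. The other probe set of Osbpl1a was at 0.55 and did not pass, and of 7 other Ighm probe sets 1 passed. Those of Serpini1, Bmi1 and Gnai1 passed in the same direction.

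The change from day 7 to day 46 or 49 was averaged over both studies (7 specimens of day 7 and 6 of the later days). Klra17 (2.86, SE 0.46, adjusted p = 0.001) and Gpnmb (2.60, SE 0.34, adjusted p = 1.6e-05) led the increases outside the immunoglobulin genes. They were followed by the matrix genes Ccn3 (2.09, SE 0.42) and Fmod (1.91), the mesothelial gene Upk3b (1.82, SE 0.41) and the matrix-degrading enzyme gene Mmp3 (1.68, SE 0.32). Car3 fell by 3.56 (SE 1.00), Cd163 by 2.21 (SE 0.36), Retnla by 1.90, Malat1 by 1.60 (SE 0.38), the splicing gene Prpf19 by 1.39 and Pdap1 by 1.35. The Car3 call was near the threshold (adjusted p = 0.049) and held with 3 of 13 specimens left out in turn, that of Retnla with 9, that of Malat1 with 11 and that of Cd163 with all 13. With RNA quality as a covariate Car3, Retnla, Malat1, Pdap1, Ccn3 and Upk3b did not pass. Over all settings Ccn3 stayed between 1.83 and 2.43, Upk3b between 1.38 and 2.02 and Car3 between −5.3 and −2.79. The sizes of these genes thus stayed large where the call was lost. Retnla (−2.02 to −1.14), Malat1 (−1.76 to −1.11) and Pdap1 (−1.48 to −0.74) shrank more at their smallest. Edem2 rose by 1.44 (SE 0.27) and the B cell gene Cd22 by 1.06. Immunoglobulin genes rose in 4 and fell in 1 of 17 (7 and 2 adjusted over the list alone, median 0.53, adjusted p = 0.0102, adjusted p = 0.491 with an estimated correlation). Igkv6-14 was at 3.22 (SE 0.73), Igha at 2.59 (SE 0.69) and Ighm at −1.84 (SE 0.52), for which 4 other probe sets were past the threshold in the opposite direction. With 1 specimen left out the Ighm call held in 2 of 13 cases and those of Igha and Cd22 in 7 and 6.

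Matrix remodelling genes rose in 3 of 12 (7 adjusted over the list alone, median 0.70, adjusted p = 8.72e-05, adjusted p = 0.482 with an estimated correlation). These were Mmp3, the protease gene Adam8 (1.17) and Mmp2 (1.11). No list of this comparison was tested without the compressed array of day 49. The balance of the directions over all genes depended on that array, as given below. Myc targets and ribosome biogenesis genes were lower as a group (median −0.45, adjusted p = 0.00014, adjusted p = 0.872 with an estimated correlation). Of the 24, 1 fell, Nolc1 (−1.07, SE 0.26), and 8 did adjusted over the list alone. Cell cycle genes were lower as a group as well (median −0.42, 0.00014, adjusted p = 0.872 with an estimated correlation). Of the 23, 1 fell, Mcm4 (−0.95, SE 0.26), also adjusted over the list alone. Mesothelium genes rose in 2 of 9 (3 adjusted over the list alone, 0.0102), with Msln at 1.11, and neutrophil genes in 2 of 12 (3 adjusted over the list alone, 0.0126), with Mmp9 at 1.27 and Csf3r at 0.75. Both lists had adjusted p = 0.872 with an estimated correlation. With 1 specimen left out Msln held in 2 of 13 cases, Mmp2 and Mcm4 in 4 and Mmp9 in 6. Adipocyte genes fell in 1 of 9 (4 adjusted over the list alone, 0.0209, adjusted p = 0.872 with an estimated correlation). Oxidative phosphorylation genes were lower as a group with 0 of 14 past the threshold (also 0 adjusted over the list alone, median −0.38, 0.0209). Their value was adjusted p = 0.969 with an estimated correlation. Myc did not pass (0.31, adjusted p = 0.56).

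263 genes passed this comparison, 144 up and 119 down, 48 and 30 of them at least 2-fold. The balance of the directions did not hold, with 579 up and 133 down when the compressed array of day 49 was left out, 53 and 7 with RNA quality as a covariate, and 178 and 551 without specimen 1 of day 49. The captured cells of day 49 had a 3-prime to 5-prime difference of 3.37 ± 1.09 (SD, lowered by the compressed array) against 4.66 ± 0.29 at day 7 of study 2. Those of day 46 had 4.07 ± 0.91 against 4.44 ± 0.60 at day 7 of study 1. No fit with this difference as a covariate left the compressed array out. With this difference as a covariate 60 genes passed, with arrays entered singly 434, with arrays entered singly and the period of the dates in the titles of the study 1 arrays as a term 28, and with the compressed array of day 49 left out 712. Captured arrays of days 7 and 46 of study 1 share no such period, so that the period overlaps with the day. Klra17, Gpnmb, Mmp3, Cd163 and Edem2 passed under every setting. Leaving out 1 specimen gave 153 (code 5) and 137 (code 8) at day 7 of study 1, 93 (middle code) and 99 (highest code) at day 46, 95 and 147 (specimens 1 and 2) at day 7 of study 2, and 729, 535 and 867 (specimens 1, 2 and 3) at day 49. Of 100 splits of the specimens (the real one included) 5 gave at least the real count, up to 1296, so that chance is not excluded for the count.

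In whole granuloma the days were compared to follow the tissue as a whole, which includes the plasma cells. From day 7 to day 105 of study 2 (3 specimens each) Klra17 rose from 6.39 ± 0.50 to 12.74 ± 0.48 (6.34, SE 0.68, adjusted p = 8.1e-08). Serpini1 rose by 3.29 (SE 0.49), Tnfrsf13b by 2.75 (SE 0.41), Nbea by 2.74 (SE 0.40), the tight junction gene Cldn7 by 2.71 (SE 0.60) and Ly6d by 2.64. Smooth muscle genes fell in 9 of 9 (9 adjusted over the list alone, median −3.93, adjusted p = 3.43e-08, adjusted p = 0.456 with an estimated correlation). The myosin light chain gene Myl9 fell from 12.92 ± 0.58 to 7.45 ± 1.66 (−5.47, SE 0.93), Actg2 by 4.88, Cnn1 by 4.65 and Myh11 by 4.49 (SE 0.85). Thrsp fell by 4.53 (SE 1.20), the macrophage chitinase-like gene Chil3 by 4.20 (SE 0.74) and the retinol carrier gene Rbp4 by 4.08. The imprinted gene Plagl1 fell by 4.05 (SE 0.58), Acaa1b by 3.86 and the fatty acid binding gene Fabp4 by 3.51 (SE 0.58). Plasma cell genes rose in 7 of 17 and fell in 0 (7 adjusted over the list alone, median 0.77, adjusted p = 0.000276, adjusted p = 0.697 with an estimated correlation). Among them Prdm1 rose by 2.10 (SE 0.46), the plasma cell transcription factor gene Irf4 by 1.56 (SE 0.46) and Eaf2 by 1.47 (SE 0.53), whose call held with 1 of 6 specimens left out in turn. Tnfrsf13c rose by 2.54 (SE 0.33).

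Other lists of whole granuloma moved with these. Adipocyte genes fell in 5 of 9 (7 adjusted over the list alone, median −2.09, adjusted p = 0.000459), with Plin4 at −2.93 and Cidec at −2.94. Fibroblast and collagen matrix genes fell in 8 of 19 (8 adjusted over the list alone, 0.000459), with Postn at −2.86 (SE 0.37) and Dpt at −2.72. Both lists had adjusted p = 0.697 with an estimated correlation. Mesothelium genes fell in 5 of 9 (6 adjusted over the list alone, 0.00658, adjusted p = 0.697 with an estimated correlation), with Krt8 at −2.71 and Krt19 at −2.13. Cell cycle genes were higher as a group (median 0.47, 0.0036, adjusted p = 0.757 with an estimated correlation), with 1 of 23 past the threshold (Kif11, 1.34, SE 0.34), also adjusted over the list alone. Of 3 intestinal epithelium genes Cldn7 and Epcam (1.53) rose (2, also adjusted over the list alone, 0.0477, adjusted p = 0.456 with an estimated correlation). The chemokine genes Cxcl1 (−2.38), Ccl9 (−2.35) and Ccl2 (−1.95, SE 0.39) and the NF-kB gene Relb (−1.84) fell. Of the secretion genes Sel1l rose by 2.22 (SE 0.39) and Edem1 by 1.78 (SE 0.44). Ighm fell by 3.92 (SE 0.76) on its chosen probe set, while 4 other Ighm probe sets rose by 3.26 to 4.42 and 1 fell by 4.38. Its day 7 values were the highest of their arrays, so that the size is not exact. With 1 specimen left out the Epcam call held in 2 of 6 cases and that of Cidec in 4. Myc did not pass (0.74, adjusted p = 0.22).

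1627 genes changed from day 7 to day 105 in whole granuloma of study 2, 520 up and 1107 down, 307 and 842 at least 2-fold. 1133 of them (69.6%, against 56.5% of all genes) had the same sign in study 1, where 0 genes passed on their own in limma (243 at an unadjusted p of 0.05, 1 specimen at day 104). Over all days 2099 genes changed in study 2 (3257 unadjusted). Entpd1 (8.84 ± 0.09 at day 7, 11.09 ± 0.09 at day 105), Klra17, Sncg (8.59 ± 0.43 and 6.18 ± 0.25), Slc12a8, Gstm2 and Arsg had the smallest p-values. In study 1 only 3 genes passed over the days (273 unadjusted), and whether the studies differ was not tested. They were Nr4a1, an early response gene (10.09 ± 0.72 at day 7 and 7.62 ± 0.15 at day 17, n = 2, limma adjusted p = 0.0015), the hyaluronan synthase gene Has1 (8.86 and 5.91, adjusted p = 0.0095) and Pnpla3, a gene of lipid metabolism (7.47 and 5.70, adjusted p = 0.0095). The 3-prime to 5-prime difference of whole granuloma in study 2 was 1.72 ± 0.04 (SD) at day 7 and 1.55 ± 0.15 at day 105. In simulated data 14.8% of the calls of the day 105 comparison and 19.1% of those over all days of study 2 fell on unchanged genes. The day 105 count was 960 without specimen 2 of day 7, and 823 and 940 without specimens 2 and 3 of day 105. The count over all days of study 2 was 977 and 1144 without specimens 2 and 3 of day 105, and 735 with only its whole granuloma arrays in the fit. The count of 3 in study 1 was 6 without specimen 3 of day 7, 1 without specimen 1 of day 7 and 0 with only its own arrays in the fit. 35 of 100 splits of the study 1 specimens (the real one included) gave at least 3, up to 27, so that chance is not excluded there.

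Whether captured cells and whole granuloma changed alike from day 7 to day 105 of study 2 was tested as the difference between the changes (3 specimens per group). The muscle genes Myl9 (difference 4.76, SE 1.20, adjusted p = 0.029), Sh3bgr (4.69, SE 1.10), Cnn1 (4.47, SE 1.30), Myh11 (4.46, SE 1.10) and Tnnt2 (4.36) and the calmodulin regulator gene Pcp4 (4.02) led the positive differences. With 1 specimen left out the calls of Cnn1 and Pcp4 held in 0 of 6 cases, those of Myl9, Myh11 and Tnnt2 in 2 and that of Sh3bgr in 3. Each fell in whole granuloma, by between 4.14 and 5.47, and moved by −0.71 to 0.11 in captured cells, where the levels were low (Myl9 4.84 at day 7). Negative differences were led by Kdm5a, a histone demethylase gene (−3.31, SE 0.65, adjusted p = 0.0065). It fell by 2.10 in captured cells and was at 1.21 (adjusted p = 0.0792) in whole granuloma. The splicing gene Rbm25 (−3.10, SE 0.60) fell by 1.71 in captured cells and rose by 1.39 in whole granuloma. Its 3 other probe sets did not pass for the difference (−1.3 to 0.58). The chromatin gene Atrx (−2.70), the mitosis gene Cenpe (−2.69, SE 0.55), Akap9 (−2.57) and Sbno1 (−2.55) followed. Kdm5a, Rbm25 and Cenpe held in 4 of 6 cases, Sbno1 in 3 and Atrx and Akap9 in 1. Plin4 (2.67, SE 0.61), Upk3b (2.97, SE 0.79) and the lymphotoxin receptor gene Ltbr (1.47, SE 0.35) had positive differences and Il6ra (−1.94, SE 0.55) a negative one, which held in 1 of 6 cases against 2 for the other 3. Another Il6ra probe set did not pass (−0.09). Igha (3.51, SE 1.30, adjusted p = 0.13), Ighm (−2.58, SE 1.00, adjusted p = 0.14), Klra17 and Myc did not pass. For Ighm the day 7 values lay at or near the top of the arrays in both tissue types.

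Smooth muscle genes passed this test in 6 of 9 (8 adjusted over the list alone, median 3.79, adjusted p = 1.54e-06, adjusted p = 0.869 with an estimated correlation). Mesothelium genes passed in 1 of 9 (6 adjusted over the list alone, median 1.76, 0.0015, adjusted p = 0.869 with an estimated correlation). Pancreatic acinar genes were negative as a group with 0 of 9 past the threshold (also 0 adjusted over the list alone, median −2.06, 0.000563), as were cell cycle genes (0 of 23, also 0 adjusted over the list alone, median −0.34, 0.00925). Both had adjusted p = 0.869 with an estimated correlation. Without specimen 1 of day 7 the acinar list was not past the threshold (median −0.12, adjusted p = 0.712), and the median of the cell cycle list was −0.53. The interferon response list was positive as a group (0 of 13, 3 adjusted over the list alone, median 1.10, 0.046, adjusted p = 0.869 with an estimated correlation). 293 genes passed, 250 positive and 43 negative, 245 and 42 of them by at least 2-fold. With only the specimens that have both tissue types and their code as a fixed replicate block the count was 26. It was 18 with only the arrays of study 2 in the fit and 669 with the compressed array left out. Leaving out 1 specimen gave 1, 68 and 501 (specimens 1, 2 and 3 of day 7) and 1 and 13 (specimens 2 and 3 of day 105).

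The difference between captured cells and whole granuloma varied over the 5 days of study 2 in 633 genes (limma F test, 2466 unadjusted). Sncg had the smallest p (adjusted p = 0.00047), with a difference of −3.75 (SE 0.26) at day 7 and −1.06 at day 105 on quantile-normalized values. The zinc finger gene Zfp148 (0.00047) was at 1.40 and −0.29 on those days, and Csnk1g2 (0.00081), a casein kinase gene, at −1.09 and 0.56. Zfp943 (0.00081) was at −0.39 and 1.81, Zfp931 (0.00082) at −0.78 and 1.48, and Rrp7a (0.001), a gene of ribosome assembly, at −0.96 and 0.36. With only the specimens that have both tissue types and their code as a fixed replicate block the count was 4. It was 342 with quantile-normalized values, 17 with only the arrays of study 2 in the fit and 1207 with the compressed array left out. Leaving out 1 specimen gave 251 and 336 (specimens 1 and 2 of day 7), 419 (specimen 3 of day 17) and 215, 283 and 232 (specimens 1, 2 and 3 of day 33). It gave 1707, 1002 and 2145 for specimens 1, 2 and 3 of day 49 and 295 for specimen 2 of day 105.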

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

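The tests of the explanations weighed here were chosen after the results were seen, and the counts over other splits of the samples were planned before. Each result was singled out because 1 sample lay far from the others of its group or because an effect differed between groups by its own test, except the fall of Ighm and the low Y-linked transcripts, which were chosen after their values were seen.

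Among the 10 groups of 4 to 10 arrays, 4 measures per array were tested for a sample far from the rest (40 tests, of which chance singles out about 1 in 20), and 7 were. In captured cells of day 49 of study 2, replicate 4 had a median of 5.641 (others 5.341 to 5.395), a 99th percentile of 8.697 (others 12.45 to 12.55), a 3-prime to 5-prime difference of 0.463 (others 3.78 to 4.26) and a mean rank correlation of 0.247 with its group (others 0.827 to 0.833), so that its values were compressed. The median of replicate 4 of captured cells of day 33 in study 1 was 5.111 (others 5.053 to 5.066). The mean rank correlation was 0.887 for replicate 1 of captured cells of day 7 in study 2 (others 0.957 to 0.966) and 0.968 for replicate 1 of day 105 (others 0.974 to 0.977).

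Captured cells minus whole granuloma differed between the studies in 3855 genes. The largest positive differences were those of Cpb1 (3.52), Cpa1 (3.49), Serpinb6b (3.23), Zg16 (2.96), Bmpr2 (2.91) and Ctrb1 (2.89), and the largest negative ones those of Rraga (−3.71), Snd1 (−3.67), Hnrnpl (−3.62), Rsl24d1 (−3.35), Alyref (−3.34) and Coq10a (−3.32). The difference varied by day in 633 genes of study 2. The change from day 7 to day 105 differed between captured cells and whole granuloma in 293 genes, led by Myl9 (4.76), Sh3bgr (4.69), Cnn1 (4.47), Myh11 (4.46), Tnnt2 (4.36) and Pcp4 (4.02) and by Kdm5a (−3.31), Rbm25 (−3.10), Atrx (−2.70), Cenpe (−2.69), Akap9 (−2.57) and Sbno1 (−2.55).

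Muscle genes led the positive side of the last difference, and their fall in whole granuloma may come from the tissue that the sections held. Within the days of study 2 the deviations of the 9 smooth muscle genes correlated by 0.926 on average (median of 1000 random lists of the same size 0.018, 95th percentile 0.185), as a varying amount of muscle in the sections would give. RNA quality cannot be told apart from it. With the 3-prime to 5-prime difference as a covariate the median change was −3.93, as without it, but the measure hardly differed between the days (1.72 and 1.55). It shifted genes by less than their spread (95th percentile of the shift 0.0909, median SE of a change 0.308), so that it was no test. In study 1 the mean of these genes was 8.12 at day 7 and 9.07 at day 104. A biological loss of muscle from the granulomata by day 105 was not tested.

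The fall of Ighm in captured cells at day 105 was weighed against 2 technical explanations. A single faulty probe set is unlikely to account for it, since 1 other tested probe set of the gene also fell (−7.27), although 6 others did not. The scaling of the late arrays is also a poor candidate, because the change was −6.18 with quantile normalization. A switch of the plasma cells from IgM to IgA was not tested. Igha was already at 12.21 to 13.70 in captured cells of day 7 of study 1, where Ighm fell too, and at 14.20 in specimen 2 of day 7 of study 2. The call of its rise in study 2 was lost under 3 settings, of which only array weights made the rise smaller (2.33).

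In study 1, captured cells of day 104 had little transcript of the Y-linked genes Eif2s3y (3.38 to 4.64, 5 arrays) and Kdm5d (2.94 to 4.14), while whole granuloma of the same code had 7.93 to 8.42 and 6.11 to 6.93 (3 arrays). Captured cells from a female animal are a poor candidate, as the highest Xist value of the 5 arrays was 6.698, below the 10.3 to 12.5 of the 29 captured arrays of study 2. A general loss of transcripts of that abundance would rarely reach as far, since at most 1.23% of genes at a like level did (20 of 1626 for Kdm5d, 9 of 1532 for Eif2s3y). Whether the captured cells themselves hold little Y-linked transcript cannot be told, since both genes lying more than 1 below the lowest whole granuloma array in 5 of 5 arrays only restates the pattern. All these arrays come from 1 specimen, so that a mix-up of material is not excluded.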

How the results depend on the processing

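The tests of the processing were chosen before the data were examined, except those said to have been chosen after seeing the data. Of the counts under other settings 130 stayed within 1.5 times the value in the report and 80 did not, and of those with 1 specimen left out 142 did and 39 did not. These are total counts. The split by direction of captured cells against whole granuloma did not hold on the deposited values, with 44 genes higher and 8273 lower in study 2 and 17 and 5144 shared. The lone specimen of a day that leaving out another creates was assumed to vary like the other groups. Signal over background limits the folds of dim genes, and the filter, which asks for 3 averages above the median, keeps genes that are dim in most specimens. Except where a setting tests fewer genes or uses fewer samples, the cause was not tested.

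With arrays one by one and the specimen as replicate block, the counts were 1031 by day, 2251 and 557 for captured cells over the days of study 2 and study 1, 1049 for day 105 against 7 in captured cells, 434 for day 46/49 against 7, 1279 and 21 for whole granuloma over the days of study 2 and study 1, and 506 for the difference of the changes. With specimen averages and no replicate block they were 207 by day and 96 for the difference of the changes. With every array independent and no replicate block they were 3345 and 1100 (captured cells over days, study 2 and study 1), 1342 (captured cells, day 105), 653 (day 46/49), and 1332 and 45 (whole granuloma over days).

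Without a filter the difference of the changes had 192 genes. With the stricter filter, which tests 5522 genes, the counts were 3835, 3196, 2007 and 2246 (captured against whole in study 2, study 1, both and their difference), 353 (by day), 1205 and 925 (whole granuloma over days and day 105, study 2) and 94 (difference of the changes). With all probe sets, 14286 in number, they were 10066, 8782, 5258 and 6711, 1029 (by day), 2058 and 101 (captured cells over days), 1020 (captured cells, day 105), 491 (day 46/49), 3305 and 2563 (whole granuloma, study 2) and 532 (difference of the changes). With quantile normalization 342 genes varied by day and 146 differed in their change. On the values as deposited 5161 genes were shared and 6231 differed between the studies.

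With array weights the counts were 3459 (by day), 2505 and 906 (captured cells over days), 1333 (captured cells, day 105), 1014 (day 46/49), 5855 and 39 (whole granuloma over days), 3522 (whole granuloma, day 105) and 1715 (difference of the changes). With only the samples concerned they were 17, 33 and 207, 80, 142, 735 and 0, and 18 in that order without whole granuloma at day 105. With the 3-prime to 5-prime covariate, which was not run without the compressed array, they were 3452 (study 2), 1848 (both studies) and 60 (day 46/49). With arrays one by one and the period in the titles as a term, 2 choices at once, the counts were 339 for captured cells of study 1 and 28 for day 46/49. With the compressed array left out, chosen after seeing the data, they were 1207 (by day), 166 (captured cells, study 1), 966 (captured cells, day 105), 712 (day 46/49) and 669 (difference of the changes), and with only the samples concerned as well 284 (by day), 412 (captured cells, study 2) and 121 (difference of the changes). With the letter in the titles as part of the specimen code, chosen after seeing the data, they were 1153 (by day), 2156 and 87 (captured cells over days) and 11 (whole granuloma over days, study 1). With an estimated correlation the number of lists past the threshold was 0 in every comparison.

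With only specimens of both tissue types and the specimen code as a fixed replicate block, 4 genes passed by day and 26 in the difference of the changes. Captured cells against whole granuloma had 5648 genes in study 2, 3523 in study 1 and 2192 in both. The number 1 to 3 as a replicate block gave 967 (whole granuloma over days), 86 (captured cells, day 105) and 24 (captured cells over days), and correlations of −0.0276 to 0.0857 between days for 1 number do not pair the specimens.

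With 1 specimen left out the counts ranged from 5812 to 6309 (captured against whole, study 2), 4796 to 5179 (study 1), 2902 to 3513 (both), 3543 to 3862 (difference), 215 to 2145 (by day), 781 to 2989 and 27 to 64 (captured cells over days, study 2 and study 1), 128 to 801 (captured cells, day 105), 93 to 867 (day 46/49), 977 to 2851 and 1 to 6 (whole granuloma over days), 823 to 2102 (whole granuloma, day 105) and 1 to 501 (difference of the changes). Rplp0, Rps2 and Rpl8 of study 2 turned from lower to higher on the deposited values (0.381, 0.546 and 0.54 relative to the median gene) and with median centring, chosen after seeing the data (0.575, 0.74 and 0.735). Of 254 named gene results past the threshold, 154 stayed past it under every setting run and 203 with each specimen left out in turn, and no other named gene turned its direction past the threshold.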

Other observations

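The genes described next were chosen after the result was seen, and the tests on other splits of the samples were planned before.

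At day 105 of study 2 single specimens lay apart from the others of the day in some genes, in captured cells and whole granuloma. A gene was counted when it lay more than 2 on the log2 scale from the mean of the other 2 specimens, on the same side in both tissue types. Specimen 1 had 47 such genes (36 higher, 11 lower), specimen 2 had 23 (9 and 14) and specimen 3 had 17 (10 and 7), while on earlier days a specimen had 0 to 8. With captured cells of 1 specimen set against whole granuloma of another the counts were 0 to 3 at day 105, but 2 to 18 for specimen 2 of day 49, which had 7 with its own. Specimen 1 was higher for Mst1, a growth factor gene (3.51 in captured cells and 3.53 in whole granuloma), the matrix gene Ogn (4.01 and 3.02), the exonuclease gene Isg20 (3.38 and 2.82) and Cldn7 (3.20 and 2.99). Specimen 2 was higher for Bex1 (5.49 and 3.75), Clvs1 (3.45 and 4.31) and the Notch ligand gene Dll3 (2.43 and 2.79), and specimen 3 for Asb4 (4.76 and 3.73) and the receptor gene Gfra3 (2.88 and 2.83).

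Immunoglobulin transcripts also marked single specimens. Ighg3, an IgG heavy chain gene, was at 13.25 in captured cells of the day 46 specimen with the middle code, 11.40 in code 14 of day 33 and 10.51 in specimen 1 of day 105 of study 2, whose whole granuloma had 11.18. Whole granuloma of code 14 had 13.16 and that of code 16 of day 33 had 13.45. In the day 104 specimen the tissue types went opposite ways, with 13.19 in whole granuloma and 4.91 in captured cells. Cpb1, a pancreatic enzyme gene, was at 10.97 in captured cells of specimen 1 of day 7 of study 2 and at 4.62 in its whole granuloma. Eif2s3y was at 8.40 in whole granuloma of code 12 of day 17 of study 1, where the captured cells of the code had 8.25. The captured cells of code 5 of day 7 had 5.27 as the mean of 2 arrays that differed.

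Other splits of the samples into groups of the same sizes were compared with the real counts, the real split included. Chance is an unlikely source of the count for captured cells against whole granuloma in study 2 (1 of 100 splits gave at least as many, real 5998, highest other 3907), study 1 (1 of 100, 5197 and 3303) and both studies (1 of 100, 3139 and 524). The splits for the difference of the studies (1 of 100, 3855 and 1) mixed the studies within a tissue type and day. Any general shift between the studies then enters the spread, so that these splits cannot exclude chance for the difference. Few splits reached the real count for whole granuloma over the days of study 2 (1 of 100, 2099 and 2061). The same held for the variation by day (2 of 100, 633 and 721). It also held for captured cells over the days of study 2 (3 of 100, 1304 and 1970) and study 1 (2 of 100, 51 and 83). For the variation by day and for captured cells another split gave more genes than the real one. Chance is thus unlikely there but not excluded. Chance was also not excluded for whole granuloma over the days of study 1 (35 of 100, 3 and 27) and for day 46/49 against day 7 (5 of 100, 263 and 1296). Why some splits call more genes than the real one was not tested. For day 105 against day 7 there are 10 splits, too few for a share under 0.05, with 586 and 4 in captured cells, 1627 and 173 in whole granuloma and 293 and 0 for the difference of the changes.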
